A study of Schizosaccharomyces pombe with 4 samples.

How the data were processed

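Chromatin immunoprecipitation with hybridisation to 2-colour tiling arrays was measured in Schizosaccharomyces pombe on 4 arrays, 1 for each of Taz1_wt, Taz1_GFP, Taz1_L593F and Rif1_Myc. Per the labels, immunoprecipitated DNA carried Cy5 and whole-cell extract DNA carried Cy3 on each array, so no dye swap was available. The array is a custom Agilent design of 60-base probes at a spacing of 300 bp. It held 18457 probes on chromosome I, 14836 on chromosome II and 7958 on chromosome III, and also 110 probes of a mating-type contig, 61 of the mitochondrial genome and 129 of pNSU plasmid clones. The genome build of the probe positions is not given in the sources used here.

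Per the file headers, the scanner images were read with Agilent Feature Extraction 11.5.1.1, and the processed signals of both channels are an intensity, background subtracted, spatially detrended and scaled between dyes. The deposited scanner files also give the log10 ratio of red over green processed signal. The deposited series matrix gives the log2 ratio of the same signals without centring, with array medians of −0.03 for Taz1_wt, −0.05 for Taz1_GFP, −0.01 for Taz1_L593F and −0.03 for Rif1_Myc. These relations were checked on the values of all 41551 probes. Mean spot signals were not in the files, so the alternative background correction used median spot and background signals.

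The log2 ratio of processed red over green was centred on each array's median over non-control probes, with no loess and no quantile step. Spots marked as outliers by Feature Extraction were left out, 74 on Taz1_wt, 31 on Taz1_GFP, 2 on Taz1_L593F and 9 on Rif1_Myc. Signal was not well above background at 0, 1, 0 and 5 probes, and no probe was saturated. Median green signals were 26414, 15976.5, 11008 and 16855, and median red signals were 8365.5, 12307.5, 12011.5 and 5232.5. A region was a run of probes whose running median of 3 probes was at least 2-fold, with runs within 1 kb merged, and mirror regions were called in the same way at or below a log2 ratio of −1. Internal meant outside the outer 50 kb of chromosomes I and II, the centromeres and the ribosomal DNA arms of chromosome III. Centromeres were the longest interval of each chromosome without a protein-coding gene.

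Probe names give positions on an unnamed build, so the tiles were registered on assembly ASM294v3 by the correlation of whole-cell extract signal with the GC content of the tile. The registration used 7 segments with a constant shift each. In 126 of 126 windows the best shift lay within 300 bp of its segment, with a median deviation of 50 bp, and the mean r was 0.482 against 0.0669 without a shift. Names of genes, neighbours, exons, GC content and motif matches rest on it, while printed positions are those of the array. The shift is less certain in the outermost part of the left end of chromosome I, and so are gene names there. Region names use genes other than long non-coding RNAs. The genes mat2-Pc, mat2-Pi and tlh2 and 2 tRNA genes had no measured probe or no reference entry and were left out.

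The groups, the comparisons, the region rule, 8 gene lists, the motifs, the naming rule and most of the alternatives were fixed before the data were examined. The naming rule took the 10 internal regions with the highest running median of each array, the 10 lowest and 5 highest differences between Taz1_L593F and Taz1_wt, the 5 highest Rif1_Myc regions with and without Taz1, and the highest and lowest member of each gene list with taz1 and rif1. The tRNA and ribosomal protein genes of the annotation made 2 further lists. Medians over chromosome ends, centromeres and the mating-type interval were set against 10000 random blocks of internal probes. Overlaps and region means were set against 10000 circular shifts, gene lists against 10000 random lists matched on whole-cell extract signal, and motif shares against 10000 random placements. These describe each array and give no p-value between groups. Shares have Clopper-Pearson intervals at 95%, which cover counting error only.

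Region calling was tested on simulated data with 50 added regions per array and strength. At 2.5-fold it recovered 98% on Taz1_wt, 98% on Taz1_GFP, 100% on Taz1_L593F and 92% on Rif1_Myc, and at 1.5-fold 8%, 12%, 2% and 28%. Gene list medians were tested on 100 null lists, of which 3 lay above the upper bound, and on 100 lists shifted by 0.3, of which 91 did.

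Alternatives were normexp background correction with an offset of 50, the series matrix values, loess within arrays, arrays scaled to the mean MAD (median absolute deviation), filters on dim and outlier spots, no running median, thresholds of 1.5-fold, 3-fold and 4 MADs, the outer 100 kb left out, no merging, a stricter overlap, other region sources, end widths of 20 and 100 kb, gene bodies alone and other motif minimums. A fit on GC content removed from each array, and multi-copy probes left out, were added after the data were seen. Probes were taken as multi-copy where their design name ends in m, a reading that the names themselves do not state. Tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.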

Results

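Chromatin immunoprecipitation followed by hybridisation to a tiling microarray (ChIP-chip) was used to map Taz1 and Rif1 along the genome of the fission yeast Schizosaccharomyces pombe. Taz1 is the protein that binds double-stranded telomere repeats in this yeast, and Rif1 is a telomere-associated protein that also controls when replication origins fire. There were 4 arrays, with 1 array in each of 4 groups. Taz1_wt used an antibody raised against Taz1 in wild-type cells, and Taz1_L593F used that antibody in cells carrying the taz1 allele L593F. Taz1_GFP used an antibody against GFP in cells whose Taz1 carries that tag, and Rif1_Myc used an antibody against Myc in cells with Myc-tagged Rif1. Each value is the log2 ratio of immunoprecipitated (IP) over whole-cell extract (WCE) DNA, centred on the median of its array. The robust standard deviation of the log2 ratio was 0.24 for Taz1_wt, 0.28 for Taz1_GFP, 0.20 for Taz1_L593F and 0.40 for Rif1_Myc. Because a group held 1 array, no difference between groups was tested, no replicate error exists, and the number of arrays limits the precision. The SD given beside a region mean is the spread over the probes of that region on 1 array. Each array was also a slide of its own, so slide and group cannot be told apart. Positions are those in the array's probe names, whose genome build is not given in the sources used here, and gene names come from a registration of the array on assembly ASM294v3.

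The enrichment profile of each array asks where along the chromosomes the protein was recovered. Taz1 signal was high at the ends of chromosome I and at a small number of narrow internal peaks on both Taz1_wt and Taz1_GFP, whereas Rif1_Myc had many internal peaks, most of them at other places. Regions called on Taz1_L593F at a 2-fold enrichment lay only near the ends of chromosome I. Across the chromosomes, the running median of 3 probes reached 2-fold at 0.528% of probes on Taz1_wt, 1.24% on Taz1_GFP, 0.017% on Taz1_L593F and 2.09% on Rif1_Myc.

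**Figure D1:**
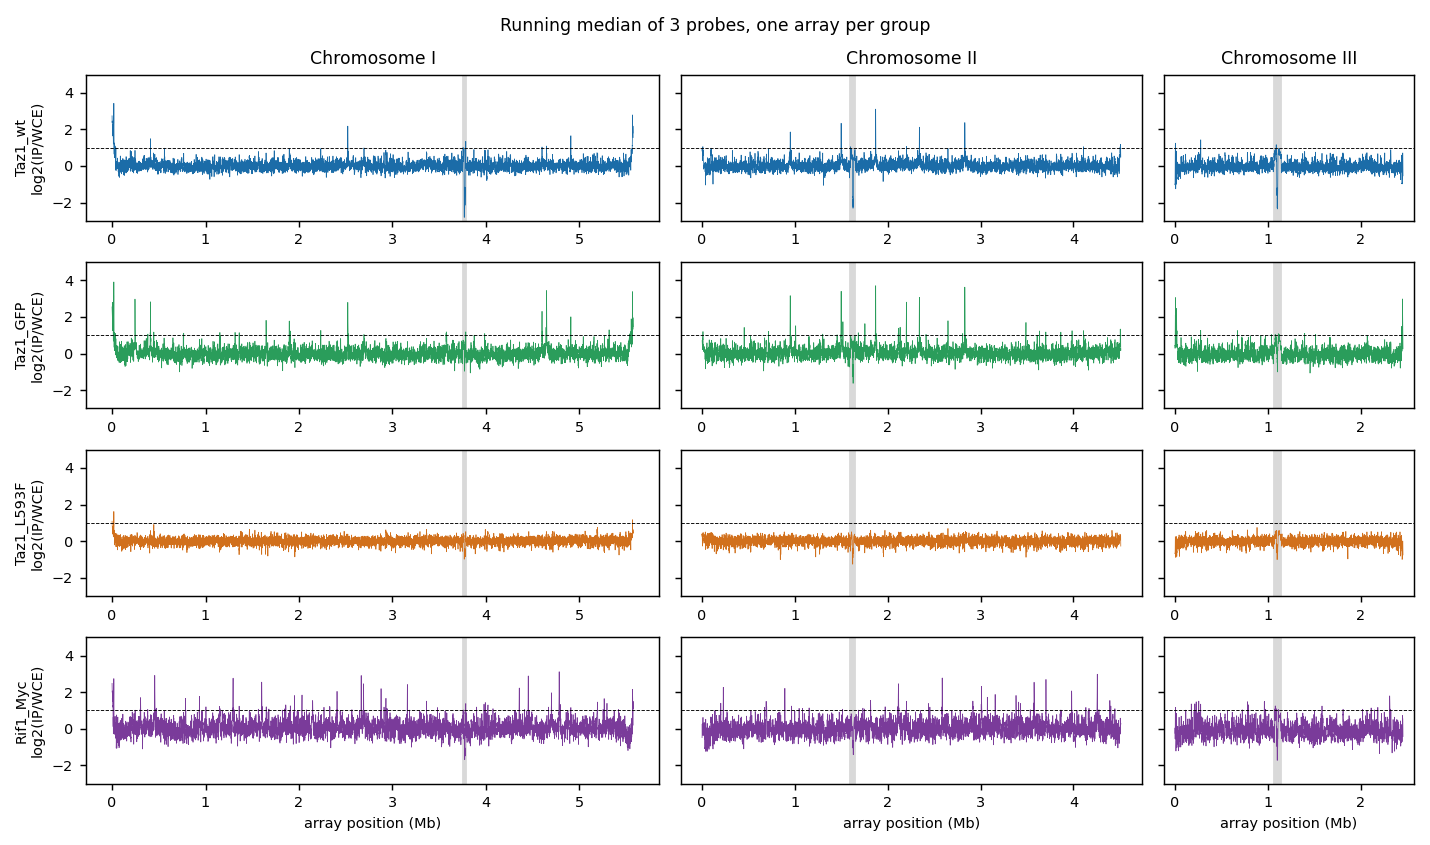
Running median of 3 probes of the log2 IP/WCE ratio (vertical axis) along the array positions of chromosomes I, II and III in Mb (horizontal axis), one row per array; the dashed line marks a 2-fold enrichment and grey marks the centromeres. Taz1_wt and Taz1_GFP share tall internal peaks on chromosome II, with summits of up to 3.11 and 3.71, that are missing from the Taz1_L593F row.

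Internal enriched regions were counted on each array outside chromosome ends, centromeres and the ribosomal DNA arms. Taz1_wt had 14 internal regions, and its highest was between erf2, which encodes a palmitoyltransferase subunit, and SPBC3H7.08C on chromosome II (1867800 to 1872000), where the running median reached 3.11, an 8.62-fold enrichment. The region next to rcr1 on chromosome II (2829600 to 2833200) reached 2.37 and the region at ivn1 on chromosome II (1497000 to 1500900) reached 2.33. Taz1_GFP had 61 internal regions, and the regions at SPBC3H7.08C, rcr1 and ivn1 reached 3.71, 3.63 and 3.40 on that array. No internal region was found on Taz1_L593F, although scaling to the mean MAD gave 3 and a 1.5-fold threshold gave 17. Rif1_Myc had 138 internal regions, led by the interval between pvg5 and SPAC22F8.03C on chromosome I (4780500 to 4786800), with a summit of 3.11, and by the interval between stb3 and SPBC1652.02 on chromosome II (4253700 to 4260900), with a summit of 2.98. Of these 138 regions, 24 held probes taken as multi-copy, against 1 region on Taz1_wt and 1 on Taz1_GFP. Such probes were 293 of 40310 internal probes, and their signal may come from more than 1 place.

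The other 7 of the 10 highest internal regions of Taz1_wt had summits from 1.31 to 2.18. They lay between gpa2, a G protein alpha subunit gene, and avl9 on chromosome I, beside coa6 on chromosome II, between gap1, a GTPase-activating protein gene of the Ras pathway, and sds23 on chromosome II, in the coding sequence of the malate transporter gene mae1 on chromosome I, beside the copper-responsive transcription factor gene cuf1 on chromosome I, in the coding sequence of the malic enzyme gene mae2 on chromosome III, and at SPBC19C7.04C on chromosome II. The 10 highest of Taz1_GFP included the regions at gap1, coa6, cuf1 and avl9 and also regions beside iec1, which encodes a subunit of the INO80 remodelling complex (summit 3.44), beside SPAC806.06C (2.97) and between cup1 and the enolase gene eno101 (2.81). After the first 2, the highest Rif1_Myc regions lay between ste7 and SPRRNA.11 (2.91), at mug114 (2.91), between the aldehyde dehydrogenase gene atd1 and cbh1 (2.88), between erv41 and the transketolase gene tkt1 (2.77), beside rga10 (2.76), between puc1 and utp4 (2.69), at SPAC23H4.05C (2.54) and at SPBC887.16 (2.54). The middle of the summit tile was intergenic in 10 of 14 Taz1_wt regions, 38 of 61 Taz1_GFP regions and 34 of 138 Rif1_Myc regions, and it lay in a coding exon in 3, 6 and 83. The shares over all internal tiles are not given here, so these counts do not show a preference. The log2 ratio correlated with GC content at r of −0.15 on Taz1_wt, −0.20 on Taz1_GFP and 0.29 on Rif1_Myc. The part of GC content in these counts was not tested.

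Regions that mirror these below the array median, at or under a log2 ratio of −1, numbered 1 on Taz1_wt, 3 on Taz1_GFP, 1 on Taz1_L593F and 27 on Rif1_Myc. On simulated data with the spread of all internal Rif1_Myc probes, signal included, the 2-fold threshold gave 54 false regions. Simulations for the other arrays gave 0 for Taz1_wt, 2 for Taz1_GFP and 0 for Taz1_L593F. At 3-fold, Rif1_Myc had 33 internal regions and 0 mirror regions. The counts moved with the processing at 2-fold: normexp gave 129 on Taz1_wt, 169 on Taz1_GFP and 6 on Taz1_L593F, and Rif1_Myc had 63 with loess and 47 after scaling to the mean MAD. They also moved with the threshold, to 148 on Taz1_wt, 288 on Taz1_GFP and 630 on Rif1_Myc at 1.5-fold and to 7 and 18 on the first 2 at 3-fold.

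**Figure D2:**
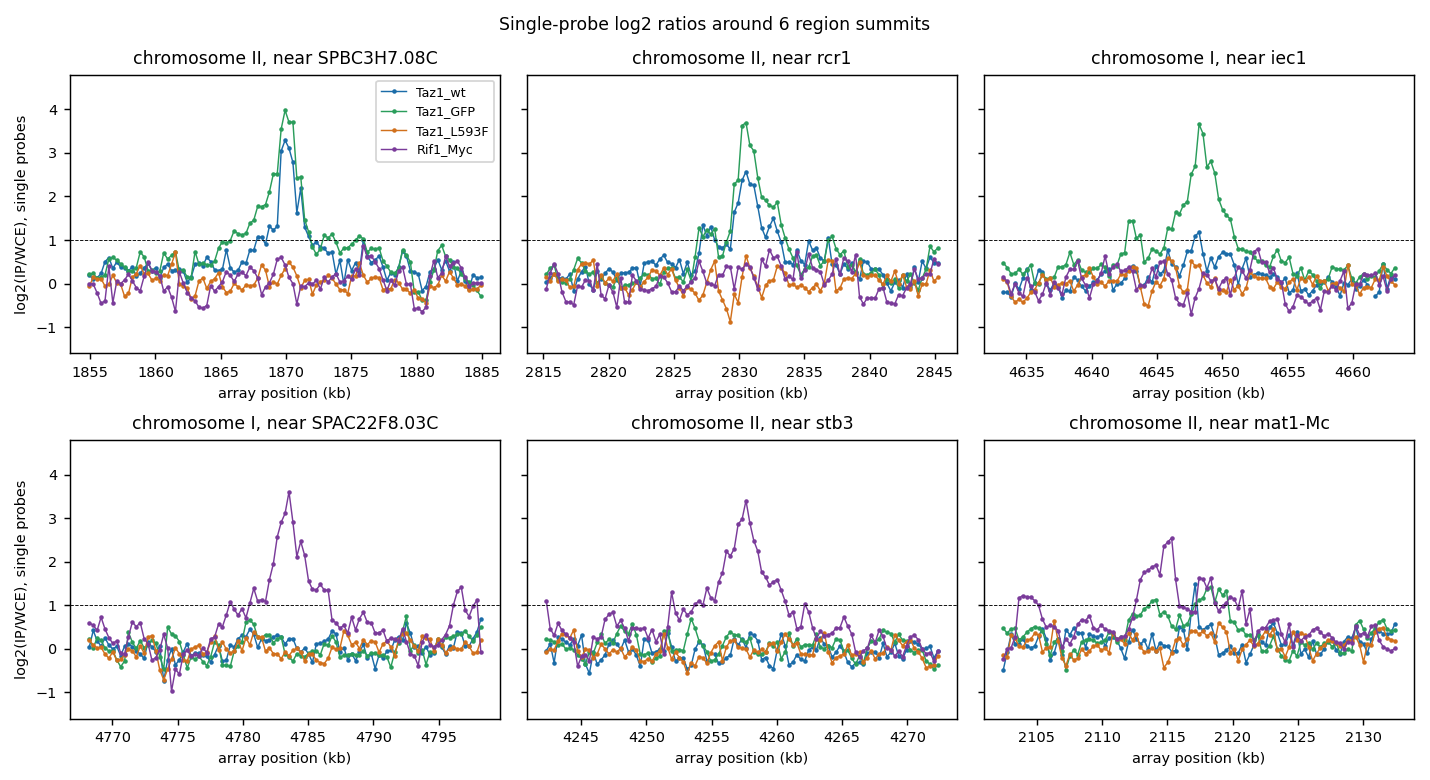
Single-probe log2 IP/WCE ratios (vertical axis) of the 4 arrays within 15 kb of 6 summits, by array position in kb (horizontal axis); the dashed line marks a 2-fold enrichment. Taz1_wt and Taz1_GFP peak together near SPBC3H7.08C and rcr1, Rif1_Myc alone peaks near SPAC22F8.03C and stb3, and near iec1 the Taz1_GFP summit of 3.44 stands far above the Taz1_wt values.

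Chromosome-end enrichment was measured over 487 probes within 50 kb of the ends of chromosomes I and II. Taken over the 4 ends, the 3 Taz1 arrays were enriched, with a median log2 ratio of 0.46 (interquartile range 0.02 to 1.02) on Taz1_wt, 0.60 (0.22 to 1.08) on Taz1_GFP and 0.23 (0.04 to 0.43) on Taz1_L593F. On Rif1_Myc the median was −0.08 (−0.39 to 0.33). The left end of chromosome I had the highest Taz1_wt median of the 4 ends, at 1.02, and the left end of chromosome II had the lowest, at 0.05, with 0.14 on Taz1_GFP and 0.14 on Taz1_L593F. The gene tlh1, which encodes a subtelomeric RecQ-type helicase, had means of 2.30 on Taz1_wt, 2.26 on Taz1_GFP, 0.76 on Taz1_L593F and 1.83 on Rif1_Myc. Enrichment fell with distance from the end. In the first 10 kb the medians were 1.92 for Taz1_wt, 1.69 for Taz1_GFP, 0.54 for Taz1_L593F and 1.12 for Rif1_Myc, and from 40 to 50 kb they were −0.05, 0.18, 0.07 and −0.29. The ends were not pooled equally, with 91 probes in the first 10 kb, 71 from 20 to 30 kb and 131 from 40 to 50 kb. The right end of chromosome II was tiled only in part, with 54 of the 487 probes and a Taz1_wt median of 0.56. Medians near the ends, also those within 20 kb, therefore rest mostly on the other ends. The 3 Taz1 medians over 50 kb were above the highest of 10000 draws of random internal blocks of that size, and Rif1_Myc was at percentile 12.7. Within 20 kb the medians were 1.501 for Taz1_wt, 1.28 for Taz1_GFP and 0.44 for both Taz1_L593F and Rif1_Myc, so the sign of the Rif1_Myc median depended on the width.

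Centromeres and the mating-type interval were compared with the rest of each array in the same way. Taz1_wt had centromere medians of 0.33, 0.47 and 0.51 on chromosomes I, II and III, Taz1_GFP had 0.37, 0.41 and 0.41, and Taz1_L593F had 0.11, 0.04 and 0.16. The Rif1_Myc medians of 0.05, 0.04 and 0.19, and the Taz1_L593F median on chromosome II, lay within the range that holds 95% of random blocks, and the others lay above it. The centromere values split by position. Probes whose design name ends in m, taken here as multi-copy, had Taz1_wt medians of 0.72, 0.71 and 0.69. The central stretch between them, set apart after its values were seen, had −1.88, −1.64 and −1.56. That central stretch was at −0.15, 0.22 and −0.10 on Taz1_GFP. With multi-copy probes left out, an alternative chosen after the data were seen, the Taz1_L593F median over all centromeres turned from 0.11 to −0.069, and with loess it was −0.067.

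The mating-type interval, from mat1-Mi to mat3-Mc on chromosome II, had a median of 0.18 on Taz1_wt, 0.44 on Taz1_GFP, 0.19 on Taz1_L593F and 0.48 on Rif1_Myc over 65 probes. The Taz1_wt value lay within the range that holds 95% of random blocks, at percentile 97.0, and the others lay above it. Beside mat1-Mc (2117400 to 2120700) the region means were 1.07 on Taz1_GFP and 1.23 on Rif1_Myc. Beside rga7 (2112600 to 2115900), next to mat1-Mi, the mean was 0.82 on Taz1_GFP and 1.88 on Rif1_Myc.

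Taz1 was mapped with an antibody against the protein on Taz1_wt and with one against a tag on Taz1_GFP, which asks whether both find the same places. All 14 internal Taz1_wt regions overlapped a Taz1_GFP region, among them those at SPBC3H7.08C, rcr1, ivn1, avl9, coa6, gap1, mae1, cuf1 and mae2. In the other direction, 13 of 61 Taz1_GFP regions overlapped a Taz1_wt region. Circular shifts of the Taz1_wt regions along the internal genome gave a mean of 0.245 overlapping regions. At the 48 regions found on Taz1_GFP alone, the median Taz1_wt region mean was 0.48 (interquartile range 0.27 to 0.65), and it was above 0 at each of the 48. The region at SPAC806.06C, 1 of these 48, had a Taz1_wt mean of 0.53 ± 0.30 against 2.11 ± 0.78 on Taz1_GFP (SD over 14 probes). The region beside iec1, which overlapped a Taz1_wt region, had 0.61 ± 0.26 against 2.08 ± 0.76 over 18 probes. Across 41149 chromosome probes, which are not independent replicates, the arrays correlated with a Pearson r of 0.499 and a Spearman rho of 0.332, beside 0.340 and 0.296 for Taz1_wt and Rif1_Myc over 41168 probes. The number of Taz1_GFP regions that overlapped Taz1_wt regions was 20 after scaling to the mean MAD, 7 at a 3-fold threshold and 75 at 1.5-fold.

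The comparison of Taz1_L593F with Taz1_wt asks what this substitution does to the recovery of Taz1-bound DNA, at regions taken from the Taz1_GFP array. Internal regions were lower on Taz1_L593F: 60 of 61 had a negative difference, with a median of −0.44 (interquartile range −0.78 to −0.32), from a median region mean of 0.53 on Taz1_wt to 0.03 on Taz1_L593F. The most negative differences were at coa6, where the mean was 1.52 ± 0.67 on Taz1_wt and 0.05 ± 0.39 on Taz1_L593F (SD over 9 probes), and at rcr1, with 1.36 ± 0.58 and −0.02 ± 0.38 over 23 probes. The end regions were lower too: over 14 of them the median difference was −0.60 (interquartile range −0.94 to −0.38), and 13 were lower on Taz1_L593F, but their median there was still 0.31, after 0.89 on Taz1_wt. Sets of probes far from the array median also lay nearer to it on Taz1_L593F: the mitochondrial median was −2.38 on Taz1_wt and −0.73 on Taz1_L593F, and that of the subtelomeric pNSU clones was 3.99 and 1.75. In the mating-type interval the medians were 0.18 on Taz1_wt and 0.19 on Taz1_L593F, while its 4 measured genes had a median of 0.42 and 0.17, an order that turned to 0.25 and 0.29 with normexp background correction.

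After coa6 and rcr1, the most negative differences were −1.36 beside the tRNA gene SPBTRNAGLU.08, −1.35 beside avl9, −1.35 at mae1, −1.34 beside gap1, −1.19 beside SPBC3H7.08C, −1.17 at mae2, −1.12 beside SPNCRNA.202 and −0.99 beside ivn1. The 5 highest differences were 0.40 at the iron-responsive repressor gene fep1, −0.003 at SPAC30C2.08, −0.01 beside mat1-Mc, −0.04 beside mat3-Mi and −0.17 at rga7. The fep1 region held 2 probes. The lowest median that 10000 circular shifts of the 61 regions gave for the difference was −0.33. With regions taken from the Taz1_wt array, which favours a fall, the median difference was −1.46 and all 14 regions were lower on Taz1_L593F.

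**Figure D3:**
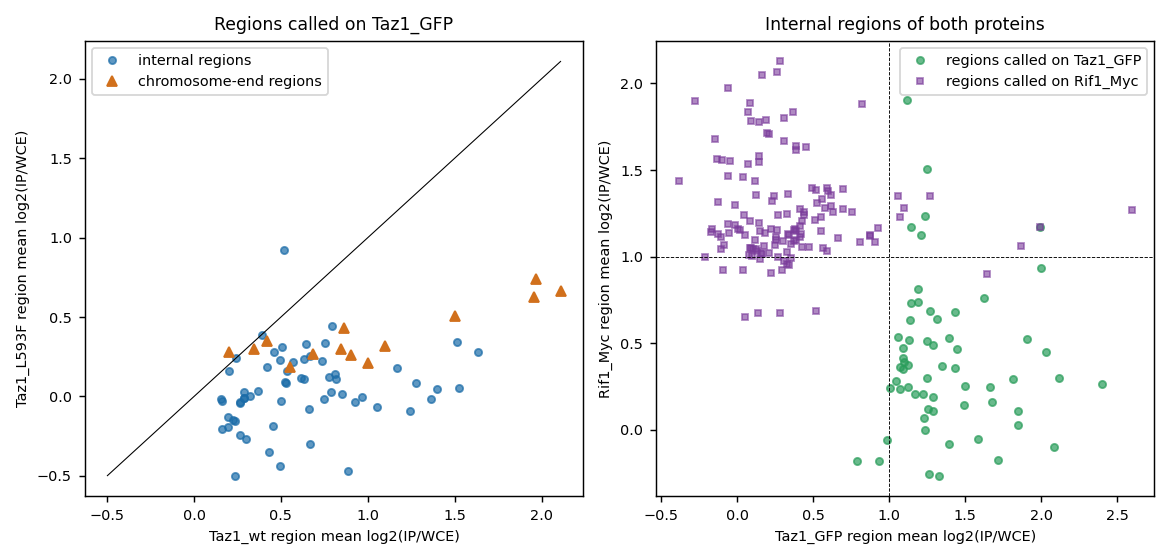
Left, region mean log2 IP/WCE ratio on Taz1_L593F (vertical axis) against Taz1_wt (horizontal axis) for the 61 internal and 14 chromosome-end regions called on Taz1_GFP, with the line of equality; right, region means on Rif1_Myc (vertical axis) against Taz1_GFP (horizontal axis) for the internal regions of either array, with dashed lines at a 2-fold enrichment. On the left 60 of 61 internal regions lie below the line of equality, and on the right the 2 sets of regions lie mostly apart.

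Rif1 was compared with Taz1 to ask whether the proteins share internal sites. Most did not coincide: of 13 internal Taz1 regions found with both antibodies, 3 overlapped a Rif1_Myc region, those at mae1, mae2 and eno101. Circular shifts gave a mean of 0.778, and the count of 3 lay at percentile 97.8 of the shifts. Over these 13 regions the median region mean was 0.27 on Rif1_Myc, 1.25 on Taz1_wt and 1.85 on Taz1_GFP. The Rif1_Myc value was above the upper bound of 0.19 in circular shifts. The tallest Taz1 region, at SPBC3H7.08C, had a Rif1_Myc mean of 0.11 ± 0.23 over 26 probes. Conversely, 129 of 138 Rif1_Myc regions overlapped no Taz1 region, with median means there of 1.16 on Rif1_Myc, 0.12 on Taz1_wt and 0.26 on Taz1_GFP.

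Of the 9 Rif1_Myc regions that overlapped a Taz1_wt or Taz1_GFP region, the 5 highest were beside utp4, rga7, mat1-Mc and eno101 and at mae2. All 9 overlapped a Taz1_GFP region, against a mean of 2.11 and an upper bound of 5 in circular shifts. The mean at mae2 was 1.58 on Taz1_wt, 1.27 on Taz1_GFP and 1.35 on Rif1_Myc over 2 probes, and the mean beside eno101 was 0.93, 2.60 and 1.27 over 6 probes. Beside utp4 the Taz1_GFP mean over the Rif1_Myc region was 0.19, so the overlap there is with a narrow Taz1_GFP region. The 5 highest without a Taz1 region were beside SPAC22F8.03C, stb3, SPRRNA.11 and atd1 and at mug114, where Taz1_wt means lay between −0.02 and 0.24. The count of 3 shared regions moved with the processing, from 0 at a 3-fold threshold to 39 at 1.5-fold.

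The gene lists fixed before the data were examined ask whether known classes of gene carried signal, with each gene taken with 500 bp on both sides. Meiotic genes of the list that holds mei4, ssm4 and rec8 were not enriched on any array: none of the 12 reached 2-fold, and the list medians were −0.03 on Taz1_wt, −0.04 on Taz1_GFP, 0.07 on Taz1_L593F and −0.07 on Rif1_Myc, with mei4 highest on Taz1_wt at 0.25 and mug9 lowest at −0.19. The mating-type genes had medians of 0.42, 0.73, 0.17 and 0.89 over 4 measured genes, led by mat1-Mc on Taz1_wt, mat3-Mi on Taz1_GFP and mat1-Mi on Rif1_Myc. Each of these mating-type medians was above percentile 99 among random lists, as was that of tlh1. The 4 genes are neighbouring pairs, while random lists draw genes one by one, so these percentiles may be too high. Among random blocks the mating-type interval was at percentile 97.0 on Taz1_wt. The 169 tRNA genes with probes had medians of 0.40 on Taz1_wt, 0.37 on Taz1_GFP, 0.04 on Taz1_L593F and 0.08 on Rif1_Myc, the last 2 of which turned to −0.012 and −0.22 with normexp background correction. The tRNA medians were at percentile 100 of random lists on each of the 4 arrays, and 4, 3, 0 and 2 of the genes reached 2-fold. The 131 ribosomal protein genes had medians of 0.26, 0.07, −0.04 and 0.24, with rps29 highest on Taz1_wt at 0.67 and rps1102 highest on Rif1_Myc at 0.94. These were at percentiles 100, 99.9, 0.03 and 100.

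The 15 highly transcribed metabolic, translation and chaperone genes had medians of 0.11 on Taz1_wt, −0.05 on Taz1_GFP, −0.18 on Taz1_L593F and 0.40 on Rif1_Myc, at percentiles 97.6, 15.2, 0 and 100. Their highest members were act1 on Taz1_wt (0.54), eno101 on Taz1_GFP (0.86) and tef103 on Rif1_Myc (0.70), and their lowest were fba1, ssa2 and hsp90 on those arrays. The Rif1_Myc value of 0.40 became 0.069 when a GC trend was removed. Histone genes had medians of 0.13, 0.11, −0.03 and 0.17, with pht1, which encodes the histone H2A variant H2A.Z, highest on Taz1_wt (0.68) and Taz1_GFP (0.88). Heterochromatin factor genes had medians of −0.07, −0.07, 0.03 and −0.17, with tas3 highest on both Taz1_wt (0.27) and Taz1_GFP (0.79). Replication initiation genes had medians of 0.02, 0.01, 0.03 and −0.07, with orc5 highest on Taz1_wt (0.28) and Taz1_GFP (0.55). Genes of telomere proteins had medians of −0.05, 0.05, −0.02 and −0.22, the last at percentile 0.88. The genes taz1 and rif1 themselves had Taz1_wt means of −0.12 and −0.04 and Rif1_Myc means of −0.09 and 0.00. In the lists of this paragraph, no member reached a mean of 2-fold on any of the 4 arrays.

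Motifs were searched in the reference sequence registered to each internal region with 300 bp on both sides. The published Rif1 consensus CNWWGTGGGGG was present in 30 of 138 Rif1_Myc regions, 21.7% (95% interval 15.2 to 29.6, Clopper-Pearson), against a mean of 0.918% and a highest value of 5.8% in 10000 random placements. The share was 5.56% of regions called at 1.5-fold and 69.7% at 3-fold. It was present in 0 of 14 Taz1_wt regions and 1 of 61 Taz1_GFP regions. Among Rif1_Myc regions its share depended on height: 23 of the 35 highest regions held it, 65.7%, and 1 of the 34 lowest, 2.94%. Of the named Rif1_Myc regions, those at SPAC22F8.03C, stb3, SPRRNA.11, mug114, atd1, erv41, utp4 and SPAC23H4.05C held at least 1 copy, and those at rga10 and SPBC887.16 held 0. Of 56 internal occurrences of the consensus, 39 lay inside a Rif1_Myc region. Over all 56, the median running-median log2 ratio was 1.57 on Rif1_Myc, −0.01 on Taz1_wt and 0.02 on Taz1_GFP.

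**Figure D4:**
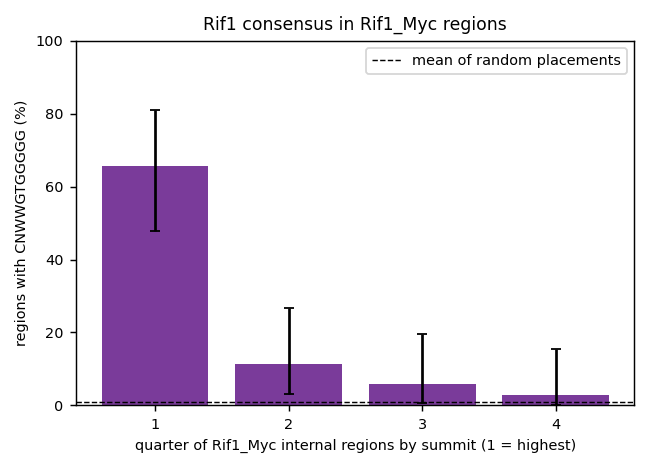
Share of Rif1_Myc internal regions that hold CNWWGTGGGGG (vertical axis, percent) by summit height in 4 groups of near-equal size (horizontal axis, 1 = highest); bars are shares, error bars are 95% Clopper-Pearson intervals and the dashed line is the mean of random placements, 0.918%. The share is 65.7% in the highest group and between 2.94% and 11.4% in the others.

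The telomere repeat core GGTTAC was present at least 2 times in 2 of 14 Taz1_wt regions (14.3%), 7 of 61 Taz1_GFP regions (11.48%) and 21 of 138 Rif1_Myc regions (15.2%), against means of 15.0%, 12.4% and 13.5% in random placements. At least 1 copy was present in 50.7% of Rif1_Myc regions, against a mean of 42.2% and an upper bound of 50%, and in 42.9% of Taz1_wt and 44.3% of Taz1_GFP regions, within their random ranges. By number of copies among the 180 orderings of its bases, GGTTAC ranked 77 in Taz1_wt regions, 82 in Taz1_GFP regions and 97 in Rif1_Myc regions. The named Taz1_GFP regions with the most copies were those at coa6 with 5, SPAC806.06C with 4 and avl9 with 3, and the regions at mae1 and mae2 held 0. The search rests on the registration of the array on the reference, whose windows deviated by a median of 50 bp, less than the 300 bp added on each side.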

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

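The tests of an equal dilution, of a compressed range, of symmetric array noise, and of base composition split by the Rif1 consensus were chosen after the results were seen. Probes of the pNSU clones, plasmid clones of subtelomeric DNA outside the chromosome tiling from which regions and end medians were taken, had median log2 ratios of 3.99 on Taz1_wt, 4.47 on Taz1_GFP, 1.75 on Taz1_L593F and 3.28 on Rif1_Myc over 129 probes. The clone pNSU71, 29 of these probes, had low medians of 0.13, 0.03, 0.18 and 0.28, with 27.6% of its probes at 2-fold on Taz1_wt. The clones pNSU77 and pNSU68 were mixed too, with 54.2% of 24 and 50% of 2 probes at 2-fold on Taz1_wt. Of the 129 probes, 88 were taken as multi-copy. The pooled values drew notice because they lie above the upper limits that few internal probes pass, which were 0.56, 0.69, 0.39 and 0.97.

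Internal Taz1 regions were lower on Taz1_L593F than on Taz1_wt. An equal dilution of the immunoprecipitate by other DNA would leave 1 ratio of enrichment over background (linear ratio minus 1) at all loci. At probes with Taz1_GFP running medians of 1 to 3, the ratio of Taz1_L593F to Taz1_wt was 0.0521 internally and 0.171 at the ends. The difference of −0.119 (95% interval −0.270 to −0.0327, bootstrap over 5 kb blocks) argues against equal dilution as the whole cause. In that window Taz1_wt medians still differed, at 0.66 internally and 1.74 at the ends. With Taz1_wt running medians of 1 to 3 instead, the difference was −0.117 (−0.167 to −0.0624). This choice uses the divisor of the ratio and can lower the ratio most near the cut-off. Taz1_wt medians there were 1.41 internally and 1.95 at the ends, so this second window adds no independent evidence. Neighbouring blocks are not independent, and these intervals hold no error between arrays. Scaling to the mean MAD left a median difference of −0.50, but mitochondrial probes shrank far more, to 0.307 of their Taz1_wt median, and pNSU probes to 0.438. With Taz1_wt compressed by these factors the internal difference was −0.12 and −0.22, below the lowest of 10000 shifts at −0.09 and −0.12, and the end difference was 0.04 and −0.10, so a compressed range was argued against as the whole cause internally, while it may account for a part that depends on the factor and stays open at the ends. Loss of binding by the L593F protein, less protein, differences between strains and array effects that differ by locus may each add to the rest, and with 1 array and 1 slide per group none was tested.

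Most Rif1_Myc regions overlapped no Taz1 region. Array noise symmetric about the median was argued against as the whole cause by 27 mirror regions, a count that cannot address noise skewed upward. Simulated symmetric noise gave 54 false regions, so part of the lower regions may be noise. Its spread was that of all internal probes, signal included. Such noise would give a like number of mirror regions, and the array had 27, so 54 may be too many. After a GC trend was removed, 66.7% of the regions stayed at 2-fold: 96.4% of the 28 with the Rif1 consensus and 58.4% of the 101 without it. The fitted trend alone thus did not account for the 2-fold level of most regions with the consensus. These were mostly the highest regions, and a high region can stay above 2-fold whatever part base composition has in it. The 2 shares therefore cannot be set against each other as evidence on base composition. In regions without the consensus, base composition and Rif1 cannot be told apart because the value lies between the bounds set for either. Recovery of the DNA of highly transcribed genes stays open: 6 of 129 regions held 1 of 317 listed tRNA, ribosomal protein and metabolic genes, 4.65% (95% interval 1.73 to 9.85), against a mean of 4.55% and a 95th percentile of 7.75% in random placements, so most regions held none, but the interval passes that bound, unlisted genes were not searched, and the 3 lists had Rif1_Myc medians of 0.08, 0.24 and 0.40, each at percentile 100 of random lists. Of these 3 list medians, that of tRNA genes turned to −0.22 with normexp background correction. That of the metabolic genes became 0.069 when a GC trend was removed. Binding of Rif1 away from Taz1 stays open as a biological explanation that was not tested by an untagged control. Of all 138 internal Rif1_Myc regions, 24 held probes taken as multi-copy, whose signal may come from more than 1 place.

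More internal regions were found on Taz1_GFP than on Taz1_wt. Recovery of the DNA of highly transcribed genes stays open here too: 3 of the 48 further regions held a listed gene, 6.25% (95% interval 1.31 to 17.2), above the mean of 3.20% and below the 95th percentile of 8.33% in random placements, so most held none, but the interval passes that bound, and tRNA and ribosomal protein genes had Taz1_GFP medians of 0.37 and 0.07, at percentiles 100 and 99.9. A single threshold on arrays of different range was consistent with the median Taz1_wt log2 ratio of 0.48 over these 48 regions, above the highest of 10000 shifts at 0.15. Antibody, tag and strain differ between the arrays along with the slide, so their parts stay confounded with each other, and none was tested.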

How the results depend on the processing

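The GC trend removed and the multi-copy probes left out were alternatives chosen after the data were seen. Across the alternatives, 672 values of the comparisons were classed as unchanged, 96 as moved and 4 as reversed in sign. Of the values at single named genes, 880 were classed as unchanged and 80 as moved. These classes did not count every change of sign. The Rif1_Myc chromosome-end median was −0.08 within 50 kb and 0.44 within 20 kb, and it was classed as unchanged. The cause of the changes below was not tested. Values follow the order Taz1_wt, Taz1_GFP, Taz1_L593F, Rif1_Myc where 4 are given. The median difference between Taz1_L593F and Taz1_wt stayed negative under every alternative run, from −0.25 to −1.46 at internal regions and from −0.47 to −1.52 at end regions. Normexp background correction turned the tRNA list median to −0.22 on Rif1_Myc and −0.012 on Taz1_L593F. It gave 129, 169 and 6 internal regions on the Taz1 arrays, 1.68%, 2.58%, 0.102% and 2.28% of probes at 2-fold, 49 Taz1_wt regions overlapping Taz1_GFP regions and 45 the other way, 12 Taz1 regions overlapping Rif1_Myc regions, and 81.7% of 169 internal regions lower on Taz1_L593F. It also gave list medians of 0.29 for histone and 0.45 for ribosomal protein genes on Taz1_wt, 0.25, 0.92, 0.29 and 0.58 for mating-type genes, with Taz1_L593F then above Taz1_wt, and tlh1 at 2.96, 2.66 and 0.93 on the Taz1 arrays. Loess turned the centromere median of Taz1_L593F to −0.067. It gave 63 internal regions and 1.13% of probes on Rif1_Myc, 1.098% of probes on Taz1_GFP, 1 Taz1 region overlapping Rif1_Myc regions, the Rif1 consensus in 46.0% of 63 Rif1_Myc regions, 100% of 12 end regions lower on Taz1_L593F, 0.61 for mating-type genes on Taz1_GFP, and tlh1 at 1.90, 1.93, 0.54 and 1.16. Scaling to the mean MAD gave 30 internal regions on Taz1_wt, 3 on Taz1_L593F and 47 on Rif1_Myc, with 0.812%, 0.104% and 0.768% of probes. It gave 20 Taz1_GFP regions overlapping Taz1_wt regions, 1 Taz1 region overlapping Rif1_Myc regions, the consensus in 51.1% of Rif1_Myc regions, and tlh1 at 2.70 on Taz1_wt, 1.07 on Taz1_L593F and 1.26 on Rif1_Myc. The series matrix values gave 1.89% of probes on Rif1_Myc and 100% of 13 end regions lower on Taz1_L593F. Without the running median there were 50, 117, 4 and 266 internal regions, 0.665% of probes on Taz1_wt, 1.43% on Taz1_GFP and 2.48% on Rif1_Myc, 30 Taz1_wt regions overlapping Taz1_GFP regions and 29 the other way, 9 Taz1 regions overlapping Rif1_Myc regions, and the consensus in 12.03% of Rif1_Myc regions. At 1.5-fold there were 148, 288, 17 and 630 internal regions, 76 and 75 overlaps between Taz1_wt and Taz1_GFP, 39 Taz1 regions overlapping Rif1_Myc regions, the consensus in 5.56% of Rif1_Myc regions, and 82.3% of 288 internal and 100% of 11 end regions lower on Taz1_L593F. At 3-fold there were 7 internal regions on Taz1_wt, 18 on Taz1_GFP and 33 on Rif1_Myc, 7 overlaps in either direction between the first pair, 0 Taz1 regions overlapping Rif1_Myc regions, the consensus in 69.7% of Rif1_Myc regions, and median differences of −0.91 at 18 internal and −1.52 at 6 end regions, with 100% of both lower on Taz1_L593F. At 4 MADs there were 48 internal regions on Taz1_wt, 4 on Taz1_L593F and 42 on Rif1_Myc, 22 overlaps in either direction between Taz1_wt and Taz1_GFP, and the consensus in 57.1% of Rif1_Myc regions. Regions called on Taz1_wt gave a median difference of −1.46, with 100% of 14 lower. Within 20 kb of the ends the medians were 1.501, 1.28, 0.44 and 0.44, with Rif1_Myc then above 0, after −0.08 within 50 kb. With the GC trend removed, 1.09% of probes on Taz1_GFP and 1.88% on Rif1_Myc reached 2-fold, the highly transcribed list was 0.069 on Rif1_Myc, and 100% of 49 internal regions were lower on Taz1_L593F. With multi-copy probes left out, the centromere median of Taz1_L593F turned to −0.069 and 1.84% of probes on Rif1_Myc reached 2-fold. At least 1 match of GGTTAC was present in 42.9% of Taz1_wt, 44.3% of Taz1_GFP and 50.7% of Rif1_Myc regions, the last above the upper bound of 50% in random placements, and at least 3 in 3.62% of Rif1_Myc regions. No paired analysis was possible because no label links the arrays in pairs, and slide could not be used as a block because each array is a slide of its own. Regions called on Taz1_L593F gave no value for the difference, since no internal region was found there, and the running median gave none for end, centromere and list medians, which use single probes. Signal over background did not limit the probes, as at most 5 on an array were not well above background.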

Other observations

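The sets of probes in this part were chosen after their values were seen. The 95 probes of the ribosomal DNA arms had medians of 0.89 on Taz1_GFP, −0.23 on Taz1_wt, −0.58 on Taz1_L593F and −0.10 on Rif1_Myc. The 61 mitochondrial probes had medians of −2.38 on Taz1_wt, −1.87 on Taz1_GFP, −0.73 on Taz1_L593F and −3.11 on Rif1_Myc. The 110 probes of the mating-type contig had medians of 0.30, 0.55, 0.22 and 0.50 in the order Taz1_wt, Taz1_GFP, Taz1_L593F and Rif1_Myc. The highest single-probe values in the centromeres, all on chromosome II, were 4.16, 5.14, 1.71 and 4.34 in that order. Each was taken on its own array and need not be the same probe. The central stretch of the centromeres on Rif1_Myc had medians of −1.07, −0.44 and −0.62 on chromosomes I, II and III, and on Taz1_L593F −0.73, −0.30 and −0.49.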
